A study of Homo sapiens with 29 samples.

How the data were processed

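CD2-positive leukocytes of 29 children with asthma were profiled on Affymetrix U133A arrays, 16 from low and 13 from high SES environments, per the labels. Per the labels' protocols, leukocytes were taken from fresh blood on a Ficoll gradient, CD2-positive cells were selected with magnetic beads, and total RNA was extracted on columns and labelled with biotin. The deposited values are log2 signals, 1 per probe set and array. They were made with RMA, per the submitters' processing notes, and its version and settings are not given in the sources used here. RMA subtracts background, makes the arrays' distributions alike and combines the probes of a set, so a shift shared by most genes would be removed, and small differences at low signal are compressed. The values ran from 2.87 to 15.1. No scanner files, scan dates or hybridisation batches were used here.

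The table holds 22283 probe sets. The platform annotation gave 1 gene symbol for 19071, several for 1043 and none for 2169, and 0 symbols changed through the Entrez identifier. Probe sets with several symbols were tested but not named. No genome build is named, so no coordinates are given. Left out were 68 control probe sets and 52 probe sets of genes that would show the sex of a child. Of the rest, 13298 probe sets with a mean over all arrays above the 40th percentile, a signal of 5.17, were tested, since RMA gives no detection call. For lists and named genes each of 8252 genes was represented by its probe set with the highest mean. HLA, killer receptor and immunoglobulin genes are given as group values only.

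Low and high SES were compared in limma 3.58.1 under R 4.3.3 with lmFit and eBayes, with group as the only term, two-sided, and Benjamini-Hochberg adjustment at 0.05. Probe sets whose group means differed at least 1.5-fold were counted apart from the test. The 28 gene lists, holding 594 different genes of which 411 were measured, were fixed before the data were examined, as were the comparison, the rule for named genes and most alternatives. Some genes are in more than 1 list. They were tested with camera at a preset correlation of 0.01, which takes genes of a list as nearly independent, with camera at a correlation estimated per list, and with fry. The fry test asks whether a list's genes move on balance one way, or in its mixed form either way, and does not compare a list with other genes. Scores and quality measures were compared with two-sided permutation tests of 100000 resamples (1e+05). The named genes were, per direction, the 8 with the smallest unadjusted p and the 4 with the largest difference, and the 2 members with the smallest p of each inflammation or stress signalling list and of every other list that passed.

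The model was tested on simulated data with 200 changed probe sets among 13298, at the arrays' own spread and with independent probe sets. It recovered 42%, 92%, 100% and 100% of changes of 0.25, 0.5, 1 and 2 on log2, and 4.02% of its calls were unchanged probe sets. Simulated lists of 20 genes with no difference and a correlation between genes of 0.4 were called in 48.5% of cases with the preset and in 4% with the estimated correlation, at an unadjusted p of 0.05. With a correlation of 0.1 these shares were 15.5% and 3.5%. The estimated correlations were 0.539 in the monocyte list, 0.443 in the immediate early list and 0.828 in the ribosomal list.

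Alternatives covered the filter on the mean (none, or the 60th percentile), a repeat of quantile normalization, centring of arrays, an intensity trend with a robust prior, array weights, and the replicate number of the titles as a block. They also covered covariates for RNA quality, for the cytotoxic and monocyte scores and for 5 surrogate variables, estimated by the iteratively reweighted method of the sva package written out in R, Welch and Wilcoxon tests, other fold limits, group medians and the mean of a gene's probe sets. Added after the data were seen were the title number as a covariate, fits without each array, fits without low SES 4, 5 and 6, the fold count without HLA probe sets, and 3 lists without genes shared with other lists. Low SES 4 was doubted for its monocyte score and low SES 5 and 6 for their wide deviations. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.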

Results

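Expression was measured in CD2-positive leukocytes from the blood of 29 children with asthma, 16 from low and 13 from high socioeconomic status (SES) environments, with 1 Affymetrix U133A array per child. CD2 is a surface receptor of T cells and natural killer cells, and cells carrying it were drawn from a density gradient fraction of blood with antibody-coated magnetic beads. The array reads the RNA of each gene with 1 or more probe sets, short groups of oligonucleotides. Each value is a log2 signal from robust multi-array averaging (RMA), and the arrays' medians lay between 5.55 and 5.70. The number of arrays limits the precision of every comparison. Any 2 arrays correlated at 0.950 or more over the probe sets and at most at 0.989, so no array was a copy of another. The p-values of single probe sets and of list scores set a difference against the spread between arrays, 1 per child. Those of camera with the preset correlation take the genes of a list as nearly independent, so they do not rest on that spread alone. The labels state nothing about the children beyond asthma and the SES group.

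The comparison asked whether expression differs between children from low and high SES environments. HSPA6, an inducible chaperone of the heat shock response, had the smallest p, with a signal of 7.43 ± 0.33 (SD, n = 16) in low SES and 8.09 ± 0.54 (SD, n = 13) in high SES. The difference, low minus high, was -0.67 on log2 with a standard error of 0.15 and a 95% interval from -0.98 to -0.36. TGFB1, a cytokine that restrains lymphocytes and drives tissue repair, stood 0.35 ± 0.09 (SE) higher in low SES. The histone genes H2AC6 and H2AX gave opposite differences, 0.33 ± 0.09 (SE) and -0.38 ± 0.11 (SE). None of these genes passed the test. In limma, 0 of 13298 probe sets passed an adjusted p of 0.05, the smallest adjusted p was 0.9998, and Welch and Wilcoxon tests also gave 0. At an unadjusted p under 0.05 limma returned 460 probe sets, 184 higher and 276 lower in low SES, where 664.9 are expected with no difference. With each array centred on its median the split was 257 higher and 218 lower, and after a repeat of quantile normalization 258 and 293. The Welch test returned 450 such probe sets and the Wilcoxon test 405. The median standard error of a difference was 0.07 on log2, and the 90th percentile was 0.12. In simulated data with 200 changed probe sets, all independent, 42% of changes of 0.25 on log2 and 92% of changes of 0.5 were recovered. These shares are not the power of this comparison. Real probe sets move together, and fewer changes would make the adjusted threshold stricter.

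The other genes with small unadjusted p were of varied function. On the side higher in low SES stood SERPINF1, a secreted serpin family protein, at 0.25 ± 0.07 (SE), and LPGAT1, an acyltransferase of phospholipid synthesis, at 0.50 ± 0.16 (SE). CHST7, a sulfotransferase, differed by 0.27 and SAMSN1, an adaptor protein of lymphocytes, by 0.37. PECAM1, an adhesion molecule of platelets, leukocytes and endothelium, differed by 0.34 ± 0.12 (SE), with 2 of its 3 probe sets on that side. SUGP1, a splicing protein, differed by 0.13. On the side lower in low SES stood METTL17 at -0.23 ± 0.06 (SE), GPSM3, a modulator of G protein signalling, at -0.25 ± 0.07 (SE), and FAM118A at -0.65 ± 0.19 (SE). PRPF3, a spliceosome protein, stood at -0.22, IVD, an enzyme of leucine breakdown, at -0.20, and NUDCD3 at -0.19. Their unadjusted p ran from 0.00102 for SERPINF1 to 0.00816 for SAMSN1, and every adjusted p was 0.9998. Of the 41 genes named by the rule fixed beforehand, 30 had 1 tested probe set annotated to 1 gene. Of the 11 with more such probe sets, 8 had all of them on the same side, the exceptions being PECAM1, PDE3B and TYMS. Probe sets below the filter or annotated to several genes are not in this or any other count of a gene's probe sets.

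Group means lay at least 1.5-fold apart for 10 probe sets, 2 higher and 8 lower in low SES. S100A8, a calcium-binding protein abundant in monocytes and neutrophils, was 1.80-fold higher in low SES, a difference of 0.84 ± 0.40 (SE). HLA-DQB1 was 1.59-fold higher and HLA-DRB4 2.18-fold lower, with standard errors of 0.71 and 0.59; both encode antigen-presenting chains that vary in sequence or copy number between people. FOSB and FOS, subunits of the AP-1 transcription factor, were 1.66-fold and 1.54-fold lower, and HSPA6 and FAM118A were 1.59-fold and 1.57-fold lower. The other 3 probe sets are annotated to several genes and are not named. Their differences were -0.999 ± 0.24, -0.73 ± 0.39 and -0.61 ± 0.23 (SE). The first had an unadjusted p of 2.26e-04 in limma. FOS and HLA-DQB1 were chosen after their values were seen. None of the 10 passed the limma test, and the count was 16 without the 3 low SES arrays that stood apart from the rest.

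Genes of monocytes, a blood cell that is not the main target of a CD2 selection, were higher in low SES. Of 19 measured monocyte genes 18 were higher and 1 was lower, with a median difference of 0.18. S100A8 led at 0.84 ± 0.40 (SE), CD14, a lipopolysaccharide co-receptor, stood at 0.54 ± 0.29 (SE), and CTSS, a lysosomal protease of antigen presentation, at 0.23 ± 0.12 (SE). Genes of platelets were also higher, 10 of 13 with a median of 0.13. Over 15 alternatives the platelet median ran from 0.05 to 0.21. The platelet chemokines PPBP and PF4 stood at 0.58 ± 0.24 (SE) and 0.49 ± 0.25 (SE), and the G protein subunit gene GNG11 at 0.24 ± 0.10 (SE). No member of either list passed its own test, over all probe sets or adjusted over the list alone. In camera with the preset correlation of 0.01 the adjusted p was 2.08e-05 for the monocyte list and 8.23e-04 for the platelet list. With an estimated correlation both lists had an adjusted p of 0.771. Low SES 4 had a monocyte score of 2.82 where the next array had 0.954, and without low SES 4 the monocyte median was 0.08, with an adjusted camera p of 0.00767, and of 0.893 with an estimated correlation. Without low SES 4, 5 and 6 it was 0.05 and the adjusted p 0.129.

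Chemokine and inflammatory genes were higher in low SES, with smaller medians than monocyte and platelet genes. Their mean differences, 0.19 and 0.17, lay between 0.15 for platelet and 0.24 for monocyte genes. Of 11 chemokines 8 were higher, with a median of 0.08, an adjusted camera p of 0.0365, and an adjusted p of 0.771 with an estimated correlation. Of 15 inflammatory cytokines and mediators 10 were higher, with a median of 0.05, an adjusted camera p of 0.0485 and an adjusted p of 0.771 with an estimated correlation. ALOX5AP, which presents arachidonic acid for leukotriene synthesis, stood at 0.28 ± 0.11 (SE), and ANXA5, a phospholipid-binding protein outside these lists, at 0.55 ± 0.23 (SE). PPBP and PF4 belong to both the chemokine and the platelet list, and without these 2 genes the chemokine median was 0.03 with an adjusted p of 0.370. S100A8, S100A9 and S100A12 belong to both the inflammatory and the monocyte list, and without these 3 genes the inflammatory median was 0.0067 with an adjusted p of 0.565. The inflammatory call held in 9 and the chemokine call in 17 of the 29 fits that each left out 1 array, and without low SES 4 the medians were 0.0044 (adjusted p = 0.448) and 0.05 (adjusted p = 0.249). Over those fits the inflammatory median ran from 0.0044 to 0.08 without high SES 12, and the chemokine median from 0.03 without high SES 7 to 0.18 without high SES 13. With the cytotoxic and monocyte scores as covariates the adjusted p was 0.494 for inflammatory genes and 0.191 for chemokines. Both calls also ended in camera with centring of arrays (adjusted p = 0.0596 and 0.0508) and with surrogate variables (0.147 and 0.192). The 60th percentile filter (0.110) and a repeat of quantile normalization (0.0603) ended the inflammatory call. Over 15 alternatives the inflammatory median ran from 0.0036 to 0.07 and the chemokine median from 0.03 to 0.34.

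**Figure D1:**
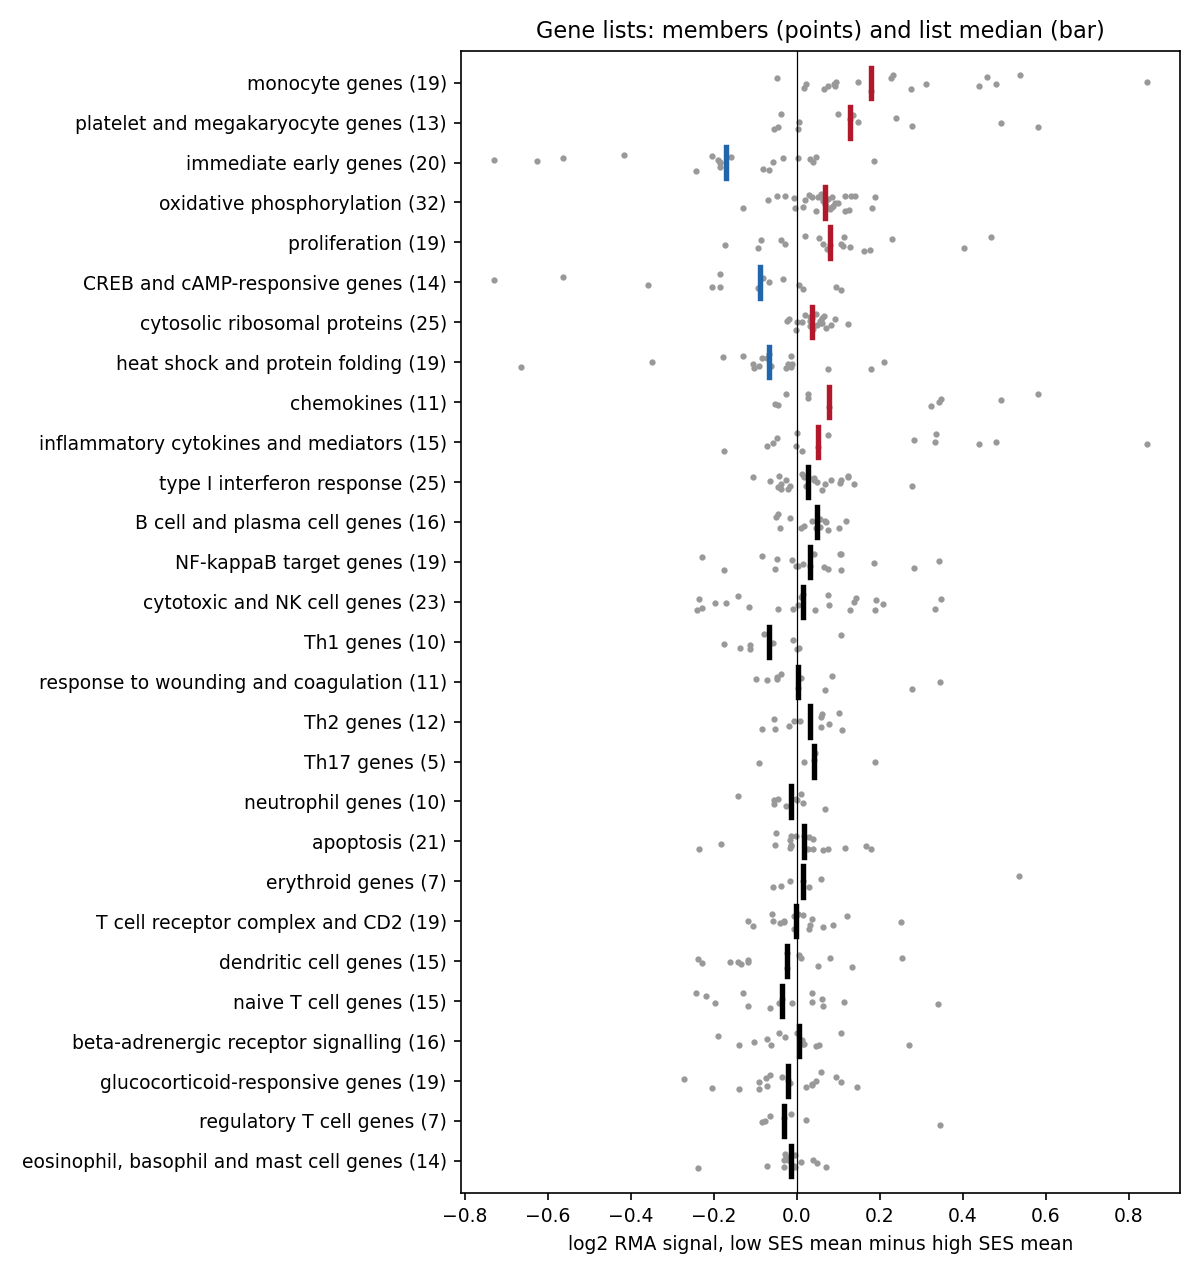
Difference of group means, low SES minus high SES, in log2 RMA signal (x axis) for the measured genes of each of 28 lists (y axis, with the number of measured genes); grey points are genes and bars are list medians, red for the 7 lists higher and blue for the 3 lists lower in low SES in camera with the preset correlation, black for the rest. The monocyte median is the highest at 0.18 and the immediate early median the lowest at -0.17, and 0 lists passed with an estimated correlation.

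Immediate early genes, transcribed within minutes of a stimulus, were lower in low SES, 15 of 20 with a median of -0.17. FOSB stood at -0.73 ± 0.26 (SE) and EGR1, a zinc finger transcription factor, at -0.56 ± 0.20 (SE). Heat shock and protein folding genes were lower, 16 of 19 with a median of -0.07, with HSPA6 in front at -0.67 and DNAJB1, a co-chaperone chosen after its value was seen, at -0.35 ± 0.16 (SE). HSP90B1, a chaperone of the endoplasmic reticulum, stood on the other side at 0.18 ± 0.07 (SE). Adjusted over the list alone, HSPA6 passed with an adjusted p of 0.00226 in limma, where over all probe sets it did not. Genes responsive to CREB and cyclic AMP were lower, 10 of 14 with a median of -0.09, and 6 of the 14 are also immediate early genes. Without these 6 the CREB median was -0.01 with an adjusted p of 0.668. Adjusted camera p-values were 9.15e-04 for immediate early, 0.0194 for CREB and 0.0205 for heat shock genes. With an estimated correlation each of the 3 lists had an adjusted p of 0.771. With surrogate variables, joined with an estimated correlation after the data were seen, the CREB median was -0.25 with an adjusted p of 0.0476. It was the 1 list that passed in that fit, which used 5 of 6 estimated surrogate variables. Joined to no filter, to the replicate block or to the RNA quality covariate, an estimated correlation let 0 lists pass. The CREB list was not fitted with surrogate variables without the 6 shared genes. Without high SES 3 the immediate early median was -0.09 with an adjusted p of 0.0514, without high SES 12 it was -0.10 and without low SES 11 -0.11, and the CREB and heat shock calls held in 24 and 21 of the 29 fits that each left out 1 array. The CREB median was -0.19 without low SES 10, -0.17 without low SES 6 and -0.14 without high SES 8, and the heat shock median -0.04 without low SES 9 or high SES 7. The CREB call ended without low SES 3, 11 or 13 or high SES 3 or 12 (adjusted p from 0.0536 to 0.180) and with the cytotoxic and monocyte scores as covariates (-0.08, adjusted p = 0.0547). The heat shock call ended with these covariates (-0.07, adjusted p = 0.0643), with the mean of a gene's probe sets (-0.04, adjusted p = 0.294) and without low SES 4, 5 and 6 (-0.05, adjusted p = 0.0727).

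Genes of 3 cell state lists were higher in low SES by small amounts. Oxidative phosphorylation genes were higher in 26 of 32 cases with a median of 0.07, led by the cytochrome c oxidase subunits COX6A1 at 0.19 ± 0.10 (SE) and COX6C at 0.18 ± 0.09 (SE). Proliferation genes were higher in 14 of 19 cases with a median of 0.08. TYMS, which makes thymidylate for DNA synthesis, stood at 0.47 ± 0.23 (SE) on 1 of its 2 probe sets with the other on the opposite side, and CCNB2, a mitotic cyclin, at 0.18 ± 0.11 (SE). Cytosolic ribosomal protein genes were higher in 22 of 25 cases with a median of 0.04, among them RPL3 at 0.12 ± 0.09 (SE) and RPS23 at 0.09 ± 0.07 (SE). Adjusted camera p-values were 0.00228, 0.0119 and 0.0194 in that order. With an estimated correlation the adjusted p was 0.857 for oxidative phosphorylation and for proliferation and 0.919 for ribosomal proteins. With the number in the sample titles as a covariate the oxidative phosphorylation median was 0.02 (adjusted p = 0.459) and the ribosomal median 0.0069 (adjusted p = 0.564). This number had a mean of 8.5 in low and 7 in high SES. Both lists rose with it, with median slopes of 0.0368 and 0.0244 log2 per number. Unequal numbers thus go with part of both median differences. After a repeat of quantile normalization the medians were 0.03 (adjusted p = 0.0800) and 0.01 (adjusted p = 0.550), and with surrogate variables they were 2.8e-05 (adjusted p = 0.883) and -0.02 (adjusted p = 0.138), with the camera direction lower for both. The oxidative phosphorylation median was 0.04 without low SES 13, 14 or 16 or high SES 4, and its call ended without low SES 16 (adjusted p = 0.108). The proliferation median ran from 0.05 without low SES 12 to 0.13 without high SES 1, and its call ended without low SES 3 or 12 or high SES 3 or 7 (adjusted p from 0.0514 to 0.0668). The ribosomal call held in 20 of the 29 fits that each left out 1 array, with medians from 0.02 without high SES 5 (adjusted p = 0.316) to 0.07 without low SES 5. The ribosomal median was also 0.02 without low SES 1, 14 or 16 or high SES 4, and 0.07 without high SES 13.

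The other 18 lists did not pass with either correlation under the settings fixed for the comparison. Type I interferon response genes were higher in 16 of 25 cases with a median of 0.03 (adjusted camera p = 0.0824), and B cell and plasma cell genes in 12 of 16 with a median of 0.05 (adjusted p = 0.150). With no filter on the mean the interferon list had an adjusted p of 0.0477, the B cell list 0.0323 and the erythroid list 0.0222, and with an estimated correlation in that setting these were 0.714, 0.714 and 0.513. The RNA quality covariate gave the interferon list 0.0335, and 0.702 with an estimated correlation. Surrogate variables gave the B cell list 0.0281 and the glucocorticoid list 0.0223, and 0.639 and 0.238 with an estimated correlation. Of the 29 fits that each left out 1 array, 4 called the interferon list (without low SES 7, 10 or 15 or high SES 8, adjusted p from 0.0115 to 0.0410), 3 the B cell list (without low SES 13 or 15 or high SES 1, from 0.0223 to 0.0410) and 1 the cytotoxic and NK list (0.12 without high SES 13, 0.0395). The adjusted p of these calls with an estimated correlation was from 0.558 to 0.780. The interferon median ran from 0.0034 without low SES 6 to 0.05 without low SES 10. Among NF-kappaB target genes 12 of 19 were higher (adjusted p = 0.370), with TNF, a cytokine, at -0.18 ± 0.13 (SE) and BCL2A1, an anti-apoptotic protein, at 0.28 ± 0.22 (SE). Wounding and coagulation genes were higher in 6 of 11 cases (adjusted p = 0.370), with F13A1, a clotting factor subunit, at 0.28 ± 0.12 (SE). Glucocorticoid-responsive genes were lower in 11 of 19 cases (adjusted p = 0.877), with FKBP5, a co-chaperone of the glucocorticoid receptor, at 0.15 ± 0.11 (SE) and SGK1, a kinase, at -0.27 ± 0.23 (SE). Beta-adrenergic signalling genes were higher in 9 of 16 cases (adjusted p = 0.877), with PRKAR1A, a protein kinase A subunit, at 0.27 ± 0.12 (SE) and PDE3B, a phosphodiesterase, at -0.19 ± 0.09 (SE) and on that side in 2 of 3 probe sets. Medians of the helper T cell lists were -0.07 for Th1 (adjusted p = 0.370), 0.03 for Th2 (adjusted p = 0.491) and 0.04 for Th17 genes (adjusted p = 0.581). Medians were -0.03 for naive and for regulatory T cell genes, each with an adjusted p of 0.877. The remaining medians were 0.02 for cytotoxic and NK (adjusted p = 0.370), -0.0028 for T cell receptor (adjusted p = 0.725) and 0.02 for apoptosis genes (adjusted p = 0.693). Neutrophil genes had a median of -0.01 (adjusted p = 0.693), erythroid genes 0.01 (adjusted p = 0.693), dendritic cell genes -0.02 (adjusted p = 0.840) and eosinophil, basophil and mast cell genes -0.01 (adjusted p = 0.894). Adjusted over the list alone, TGFB1 passed in the wounding list (0.0101) and the regulatory T cell list (0.00640) and SERPINF1 in the dendritic cell list (0.0153), in limma. The camera direction was higher for T cell receptor, dendritic and regulatory T cell genes despite their negative medians, and lower for beta-adrenergic genes despite their positive median. The means went with the test in the T cell receptor, regulatory T cell and beta-adrenergic lists, and with the median in the dendritic list.

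Scores per array, the mean of gene-wise z values of a list, set the same lists against the spread between children. The monocyte score was 0.160 ± 0.902 (SD, n = 16) in low SES and -0.197 ± 0.475 (SD, n = 13) in high SES. This difference had a p of 0.217 in a two-sided permutation test and an adjusted p of 0.977 over the 9 cell type lists. The platelet scores were 0.155 ± 0.702 (SD, n = 16) and -0.190 ± 0.255 (SD, n = 13), with a permutation p of 0.106 and an adjusted p of 0.954. Scores of T cell receptor genes differed by 0.0116 and those of cytotoxic and NK genes by 0.0614, with an adjusted p of 0.987 each. The immediate early scores differed by -0.330 (permutation p = 0.206) and the heat shock scores by -0.258 (permutation p = 0.127). Over all 28 lists the lowest adjusted p was 0.953.

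**Figure D2:**
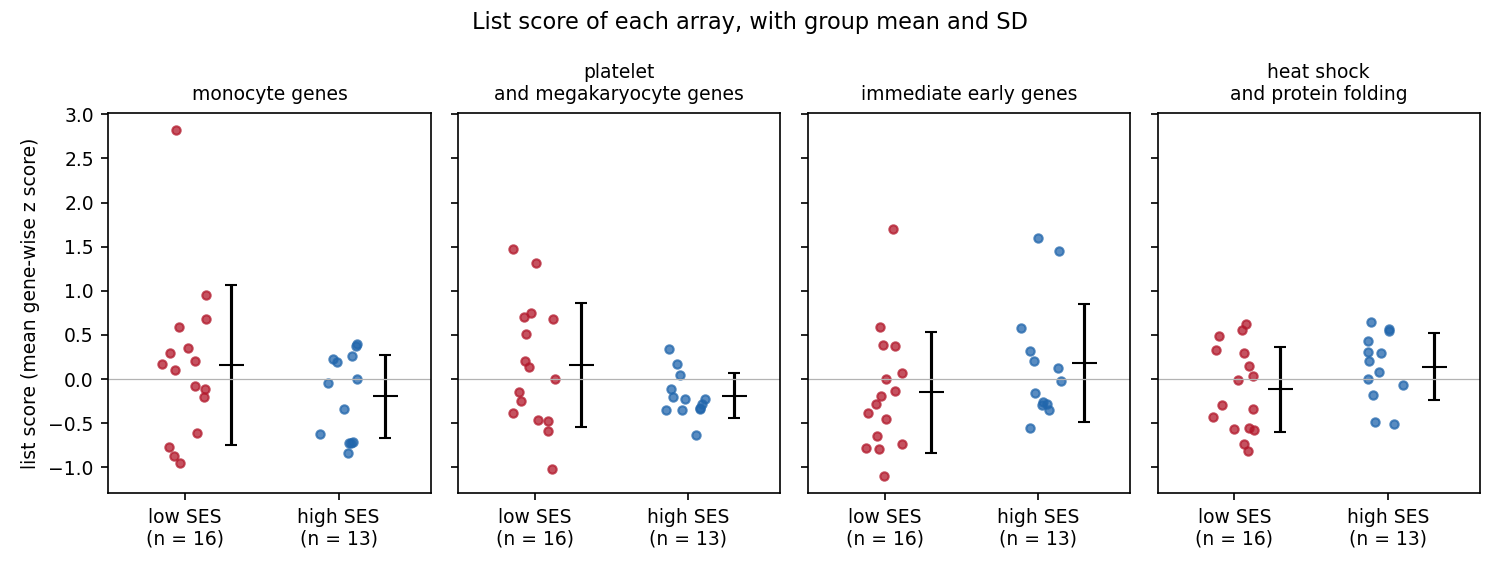
List score of each array (y axis, mean gene-wise z score, no unit) for 4 lists in low SES (red, n = 16) and high SES (blue, n = 13); points are arrays, and the black line gives the group mean with bars of 1 SD. The group ranges overlap in all 4 lists, and the highest monocyte score, 2.82, lies far above the next at 0.954.

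RNA quality by the ACTB and GAPDH controls was close in both groups. The 3' minus 5' signal of the ACTB control, which grows as RNA degrades, was 3.51 ± 0.24 (SD, n = 16) in low SES and 3.59 ± 0.22 (SD, n = 13) in high SES, with a permutation p of 0.362 and an adjusted p of 0.675. The GAPDH control gave 3.65 ± 0.18 (SD, n = 16) and 3.66 ± 0.30 (SD, n = 13), with a permutation p of 0.917. On every array the 3' signal was the higher, by at least 3.12 on log2 for ACTB and 3.08 for GAPDH. Both groups thus carried this bias. The median deviation of an array from the probe set medians differed by -0.01 (permutation p = 0.506). The interquartile range of these deviations was 0.28 ± 0.06 (SD, n = 16) in low SES and 0.24 ± 0.04 (SD, n = 13) in high SES, with a permutation p of 0.0378 and an adjusted p of 0.151 over 4 measures. The widest arrays were low SES 6 at 0.40 and low SES 5 at 0.38.

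The arrays differed along a number in their titles, 1 to 16 in low SES and 1 to 13 in high SES, whose meaning the labels do not state. The first principal component of the tested probe sets held 22.4% of the variance and correlated with this number over 29 arrays at r = 0.702 (permutation p = 4.0e-05, adjusted 2.0e-04 over 5 components) and rho = 0.690 (permutation p = 7.0e-05, adjusted 3.5e-04). Without the 2 arrays farthest from the median number r was 0.671. Within low SES r was 0.666 (permutation p = 0.00584) and rho 0.629 (permutation p = 0.0105, n = 16). Within high SES r was 0.759 (permutation p = 0.00236) and rho 0.753 (permutation p = 0.00416, n = 13). At an adjusted p under 0.05 in limma, 24 of 32 oxidative phosphorylation and 15 of 25 ribosomal protein genes rose with the number. So did 7 of 19 T cell receptor and 8 of 23 cytotoxic genes. Past the same threshold 1 cytotoxic, 4 of 10 neutrophil and 3 of 11 wounding genes fell. Of all 13298 tested probe sets 2915 passed, 2047 higher and 868 lower at higher numbers. With an estimated correlation the lowest adjusted p of a list along the number was 0.447.

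**Figure D3:**
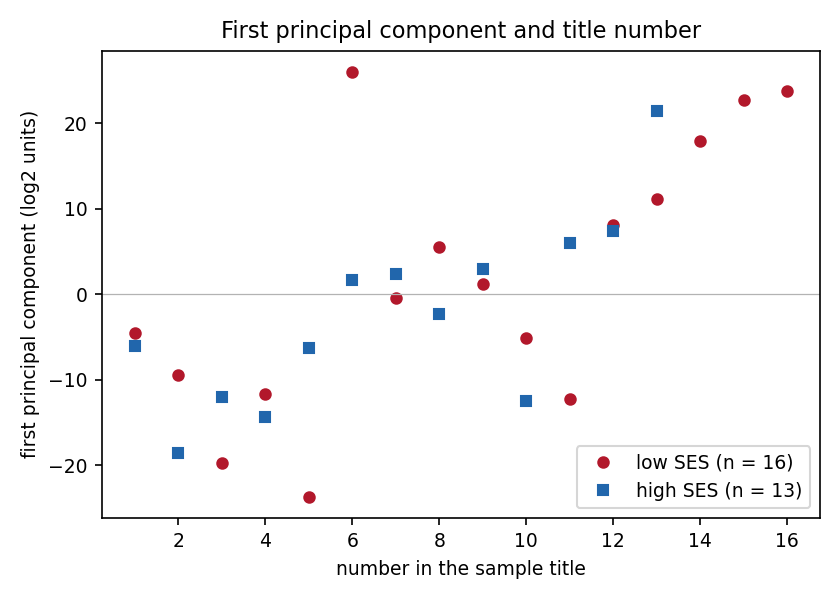
The first principal component of the tested probe sets (y axis, log2 units) against the number in the sample title (x axis, no unit) for low SES (red circles, n = 16) and high SES (blue squares, n = 13). The component runs higher at higher numbers in both groups, with r = 0.666 in low SES and 0.759 in high SES.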

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

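The leave-one-out fits, the title number covariate, the fits without low SES 4, 5 and 6, the fold count without HLA probe sets and the lists without shared genes were chosen after the data were seen, as were the fits that joined an estimated correlation with another alternative. The count of probe sets past limma stayed at 0 under every alternative run and in all 29 leave-one-out fits (0 to 0). The 10 probe sets at least 1.5-fold apart became 47 at 1.3-fold, 1 at 2-fold, 19 with group medians and 16 without low SES 4, 5 and 6. They ranged from 8 to 15 in leave-one-out fits. Of 10 lists past camera, 5 passed with cell composition covariates, where 26 lists were tested, 6 without low SES 4, 5 and 6, 0 with an estimated correlation and 0 with fry. In leave-one-out fits 4 to 12 lists passed, with 4 without high SES 3, 5 without low SES 3 and 6 without high SES 7. The cause was not tested, except that the fold limits change the count by construction and the estimated correlation, 0.0802 to 0.828 in these 10 lists, widens the camera test. The 41 named genes gave 443 values under alternatives, leave-one-out fits not included, of which 0 changed sign and 0 passed. These genes were picked for small p or large differences in the same arrays, so their unchanged signs say little. Lists gave 418 values, of which 47 lost a call, 4 of them with the direction turned, 9 gained a call and 32 were uncalled lists that changed sign.

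No label states that a title number marks a shared child, batch or day, and the pairs did not all correlate above 0.1, the bound set for pairing, so the samples are treated as sharing only a number. Of 13 pairs 8 correlated above 0.1 in their deviations, from -0.0845 to 0.247, with a mean of 0.123 against -0.0098 for differently numbered samples, and 3 of 26 samples correlated best with the sample of their own number. With the replicate block 0 probe sets passed (549 at an unadjusted p under 0.05) and 10 lists passed, not all the same. The block ended the proliferation call (0.0562, adjusted p = 0.121) and gave calls to wounding (0.0409, adjusted p = 0.00993), naive T cell (-0.0811, adjusted p = 0.00993) and B cell genes (0.0444, adjusted p = 0.0202), and with an estimated correlation in the same fit the adjusted p of these 3 was 0.380, 0.302 and 0.566. The ribosomal median was -0.0207 and the oxidative phosphorylation median -0.00108 with the block, and -0.0210 and 2.8e-05 with surrogate variables, all with camera directions lower and adjusted p between 0.138 and 0.883. The T cell receptor score difference was -0.0186 with medians of z scores, and the dendritic score difference -0.00145 with no filter on the mean, and the cause was not tested. Without detection calls, signal over background is unknown, so differences of dim probe sets can be understated.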

Other observations

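The tests of the monocyte list and of a shared order along the title numbers were chosen after the results were seen, as were all fits of the title number, the splits without doubted arrays or with the number allowed for, and the distances of splits on the first principal component. The sample titles carry a number, 1 to 16 in low SES and 1 to 13 in high SES, whose meaning the labels do not state. Over all 29 arrays, 2915 of 13298 probe sets followed this number in limma with group in the model, 2047 higher and 868 lower at higher numbers. In the list counts below, a gene rose or fell only if it passed this test at an adjusted p under 0.05. Genes not counted can have slopes on the same side. Oxidative phosphorylation genes rose with the number in 24 of 32 cases, led by the complex I subunit NDUFA1 at 0.06 ± 0.01 (SE) log2 per number and, with the next smallest adjusted p though not the next steepest slope, the ATP synthase subunit ATP5F1B at 0.04 ± 0.01 (SE). Ribosomal protein genes rose in 15 of 25 cases, among them RPL19 and RPL8. T cell receptor genes rose in 7 of 19 cases, with LCK, the kinase that starts receptor signalling, and CD3D and CD247, chains of the receptor complex, at 0.05, 0.04 and 0.05 per number. Cytotoxic genes rose in 8 of 23 cases, with NKG7 at 0.10 ± 0.03 (SE) and the granzymes GZMM and GZMA at 0.04 and 0.06, and NCR1 fell by 0.03. Neutrophil genes fell in 4 of 10 cases, among them CXCR1, LTF and LCN2, each by 0.03 per number, and wounding genes fell in 3 of 11, THBS1, PDGFB and F5. Adjusted camera p-values were 1.05e-11 for oxidative phosphorylation and 2.85e-06 for ribosomal genes, 0.0294 for T cell receptor, 0.0232 for cytotoxic, and 0.00405 for neutrophil and for wounding genes. With an estimated correlation the adjusted p was 0.447 for oxidative phosphorylation, neutrophil and wounding genes, 0.583 for ribosomal and T cell receptor genes and 0.704 for cytotoxic genes. Platelet genes had a median of -0.01 per number and an adjusted camera p of 0.0232, with 0 of 13 past the limma test and an adjusted p of 0.583 with an estimated correlation.

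Within low SES alone 223 and within high SES alone 472 probe sets followed the number, and 0 had a slope that differed between the groups (514 at an unadjusted p under 0.05 in limma). The slopes of the groups correlated at 0.60 over probe sets, above the 95th percentile of 0.459 with permuted numbers (permutation p = 0.0040). A candidate explanation is that both groups were numbered in an order shared with collection or laboratory handling. The bacterial hybridisation spikes, which hold no RNA of the children, correlated with the number at 0.0807 (permutation p = 0.677, 95% bootstrap interval -0.301 to 0.482). That value lay within the bound set beforehand against array processing, but its interval reaches well past the bound, so the reading was left open after the value was seen. Handling before hybridisation and an order of the children themselves cannot be told apart, since the labels do not say what the number counts. The arrays' median signals also differed between the ends of the first principal component. They were 5.70, 5.65 and 5.65 in low SES 5, low SES 3 and high SES 2, the lowest arrays on it. In low SES 6, 16 and 15, the highest, they were 5.55, 5.58 and 5.57. Whether the slopes on the number follow the arrays' median signal was not tested.

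The monocyte list may be higher in low SES because monocytes passed the CD2 selection in some children. Carry-over stays open: 18 of its 19 measured genes and the 5 most abundant were higher, but that restates the observation, low SES 4 included, and so does not support it. A single array as the whole source stays open, since the median was 0.0828 without low SES 4, under 0.5 of its value, while camera with the preset correlation gave an adjusted p of 0.00767. With an estimated correlation the adjusted p without low SES 4 was 0.893, and without low SES 4, 5 and 6 the preset correlation gave 0.129. Without that array the score difference was 0.180 (permutation p = 0.377). A difference in circulating monocytes between the SES groups was not tested apart from carry-over.

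Unequal title numbers (mean 8.5 in low and 7 in high SES) do not account for the lower immediate early and heat shock medians. The median slopes were 0.0136 and 0.0148 per number, which would raise both in low SES, though camera, at an adjusted p of 0.740, put the immediate early list lower at higher numbers. With the number as a covariate the medians were -0.180 and -0.0829 against -0.171 and -0.0675. At least 0.657 of either median was kept there without any 1 array. Camera with the preset correlation gave adjusted p = 0.00279 and 0.00397 with that covariate, and with an estimated correlation the adjusted p was 0.695 and 0.462. RNA degradation stays open: with the 3' minus 5' signal as a covariate the medians were -0.181 and -0.0611, but 0 probe sets followed that covariate, so the fit removes little. This test was set aside as uninformative after its value was seen. Handling time before lysis, which can induce these genes, and SES itself were not tested.

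Chance cannot be excluded for the counts: of 100 splits of the 29 arrays, the real one included, 58 gave as many probe sets at an unadjusted p under 0.05 as the real 460 (highest other 2494), 29 gave as many at least 1.5-fold apart as the real 10 (highest other 29), and 12 gave as many lists as the real 10 (highest other 12). The split with 2494 points to a structure of the samples, as its groups lay 11.3 apart on the first principal component, the 2nd largest distance of the 100 splits, against a median of 3.46 and 4.15 for the real split. Over the 100 splits, which share arrays and are not independent, count and distance correlated at r = 0.764. The spread between arrays was wider in low SES, with a median log2 ratio of SDs of 0.219 (highest other 0.228), as large in 4 of 100 splits, a share under 0.05. Another split, at -0.218, fell just short of that size, so the share is barely under its bound. With 1 array per child, spread between children cannot be told from noise of the arrays. The 100 splits ignore the title number, and numbers 14 to 16 occur in low SES alone. With the slope on the number removed the ratio was 0.220, as large in 8 of 100 splits, and over the 26 arrays with numbers in both groups 0.177, as large in 13 of 100. With both steps it was 0.248, as large in 9 of 100, so unequal numbers do not remove the ratio, but chance is not excluded once they are allowed for. In low SES 70.5% of probe sets had the wider spread. Without low SES 5, the array whose absence lowered it most, the ratio was 0.174, as large in 3 of 100 splits of the 28 arrays left. Without low SES 4, 5 and 6 it was 0.123, as large in 13 of 100 splits of the 26 left, but low SES 5 and 6 were picked for their wide deviations, which narrows the spread of low SES by construction and decides nothing.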
